A study of Homo sapiens with 12 samples.

How the data were processed

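The samples were LNCaP cells kept in 2% steroid-deprived serum. They were transfected with control or ERRγ siRNA, moved to new plates 48 h later and given 10 nM R1881 or ethanol for 72 h, with medium and treatment renewed at 48 h, per the labels' protocols. Each of the 12 samples was assigned to its group and replicate number from its own labels, with 3 arrays in each of the 4 groups. The extract protocol names Affymetrix, whereas the deposited tables have the columns and probe names of Illumina bead arrays and were treated as such. One table holds raw signal intensities per probe and array, which were neither background-subtracted nor normalized before they were deposited, per the file headers and the values. It also holds a detection p-value per probe and array, deposited by the authors, whose step sizes imply 770 negative control values. Another table holds the authors' normalized log2 values, from 7.068 to 14.1 with array medians of 7.0898 to 7.0927. Its transformation and normalization are not given in the sources used here, so its scale and floor stay unknown. The authors' deposited values in the series matrix were identical to it, with a largest difference of 0. Mean raw signal per array ran from 250.8 to 293.7, the median from 93.86 to 101.1, and 39.5% to 43.4% of probes had a detection p under 0.05. No column of per-sample values was left unused.

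Of the 47323 probes, 28588 were named by matching their RefSeq accession, without version, to current gene symbols in the RefSeq annotation of the GRCh38 assembly, which was used only for names, gene classes and the order of neighbouring genes. A further 2514 kept a symbol that is current, 1217 were updated from an older symbol, and 14643 carried only a locus or cluster name or a calendar date, 2 of them a date. Such genes were counted and not named. Raw signals were background-corrected, quantile-normalized and put on the log2 scale with neqc in limma 3.58.1, run in R 4.3.3, with an offset of 16 and the negative controls inferred from the detection p-values. Probes with a detection p under 0.05 on at least 3 of 12 arrays were kept (21959), and each gene was represented by its brightest probe. This left 17011 genes, 4070 of them unnamed and 3839 with more than 1 probe. The probes of a gene can disagree: of the genes with several probes and at least 1 called, 54 of 2414 had probes called in opposite directions for R1881 with control siRNA and 48 of 2238 with ERRγ siRNA, and 103 of 2775 for the R1881 main effect. The offset compresses low signals, so log2 changes of dim genes understate their size.

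All 12 arrays entered one linear model with a term per group, and 7 contrasts were tested with limma (lmFit and eBayes). These were R1881 against vehicle with each siRNA, ERRγ against control siRNA under each treatment, the interaction, and both main effects. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and genes with an adjusted p under 0.05 were called. Errors of log2 changes are standard errors of this model. Where a gene was not detected on any array of its dimmer group, its change is given as at least N-fold: the mean of the brighter group against, per array, the higher of the lowest detected signal and the probe's own signal. ESRRG was tested on its brightest probe although it did not pass the detection filter, with a two-sided exact permutation test as well.

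Before the data were examined, 32 gene lists, the alternatives and the rule for named genes were fixed. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, and adjusted over the 32 lists within each contrast. Fry tests whether a list's genes move on balance one way and does not compare them with other genes. A count adjusted over the list alone applies the Benjamini-Hochberg method to the list's own members. Named genes were the 8 largest rises and 8 largest falls per comparison of 2 groups among called genes whose arrays did not overlap, up to 4 members of each described list by smallest p, 11 receptor and androgen response genes, the 5 smallest p of the interaction and genes called in both main effects. Genes with near-identical copies, such as TUBA3, TRIM48 and TRIM51, UGT2B and metallothionein genes, are uncertain, since a probe may read more than 1 of them. Some genes that the rule names are not reported here.

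The alternatives were normexp with an offset of 50, no background correction, median scaling, the deposited normalized values, no detection filter or detection on all 12 arrays, the mean of probes or all probes, the replicate number as a block, trended and robust variance, array weights, fitting only the 2 groups compared, a fold threshold of 1.5, an adjusted p under 0.01, and leaving out each array in turn. Added after the data were seen were a fit with an array axis as a covariate, the first component of the residuals of the 6 R1881 arrays, a fit without the 2 arrays at its ends, and the list of solute carriers without its metallothioneins. The mixed test of fry asks whether a list's genes move in either direction. Since fry approximates it, it was also run by 99999 rotations (roast), after its values were seen. This was done only for the siRNAs under R1881 and the siRNA main effect. The chip that held each array is not given in the sources used here, so no chip block was fitted.

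The procedure was tested on simulated arrays with 50 genes changed at each of 4 sizes among 17011. At log2 changes of 0.5, 1, 2 and 3 the fit recovered 46%, 94%, 100% and 100% for R1881 with control siRNA and the same shares with ERRγ siRNA. Between the siRNAs under vehicle it recovered 44%, 90%, 100% and 100%, under R1881 58%, 94%, 100% and 100%, and for the interaction 10%, 70%, 100% and 100%. False calls numbered 6 to 12 of 16811 unchanged genes. All 4 sizes were simulated together, and the larger changes ease the Benjamini-Hochberg threshold for the smaller ones. The shares recovered may therefore be lower where few genes change. A list shifted by 0.3, oxidative phosphorylation, was recovered in each of these 5 comparisons, with 0 other lists called. The simulated genes varied independently, whereas the estimated correlation of this list was 0.157 in the real arrays. The simulation therefore cannot show how often lists are called falsely, or recovered, in the real arrays. Other tools were the data.table package (1.17.8), Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.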

Results

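RNA from LNCaP cells, an established androgen-responsive line from a prostate cancer metastasis, was measured on Illumina bead arrays. The cells had received a control siRNA or an siRNA against ESRRG, the gene of the orphan nuclear receptor ERRγ, and were then given R1881, a synthetic androgen, or its ethanol vehicle for 72 h. Each of the 4 combinations of siRNA and treatment was measured on 3 arrays, 12 in all. Between 18698 and 20536 of the 47323 probes were detected per array, with a mean raw signal of 250.8 to 293.7. Arrays of one group correlated at 0.9901 to 0.9951, arrays that differed in the siRNA alone at 0.9893 to 0.9942, and arrays of different treatments at 0.9563 to 0.9647. The first principal component, which separated R1881 from vehicle, held 73.3% of the variance. The study concerned androgen, ERRγ and the metabolism of prostate cancer cells, so R1881 was compared with vehicle under each siRNA, the siRNAs were compared under each treatment, and the difference between the R1881 effects was tested. Nothing in the labels says that the 3 samples of a group were separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision, with a median half-width of 0.253 for the 95% interval of a log2 change between groups.

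ESRRG, the target of the siRNA, was not detected on any array. Its 3 probes gave 36 array values, 0 of them with a detection p under 0.05, and the lowest detection p was 0.0623. The brightest probe, ILMN_1661994, read 4.376, 4.477 and 4.479 (normalized log2) with control siRNA under vehicle, and 4.281, 4.254 and 4.284 with control siRNA under R1881. With ERRγ siRNA it read 4.553, 4.178 and 4.23 under vehicle and 4.249, 4.197 and 4.21 under R1881. In raw signal the group means were 95.46 ± 0.707 and 92.92 ± 6.23 (SD, n = 3) with control and ERRγ siRNA under vehicle, and 93.53 ± 1.84 and 92.36 ± 0.921 under R1881. The siRNA difference was -0.12 under vehicle (limma, adjusted p = 0.732; two-sided exact permutation p = 0.4) and -0.055 under R1881 (adjusted p = 0.973; exact p = 0.1), where 0.1 is the smallest p that 3 against 3 can give. The R1881 difference was -0.17 with control siRNA (adjusted p = 0.267; exact p = 0.1) and -0.10 with ERRγ siRNA (adjusted p = 0.6; exact p = 0.7). These readings lie at background, so the arrays give no measure of the knockdown, nor of whether R1881 alters ESRRG. ESRRA, the gene of the related receptor ERRα, was detected on all 12 arrays, ESRRB on 1 array, and the coactivator genes PPARGC1A and PPARGC1B on 0 arrays and 1 array.

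**Figure D1:**
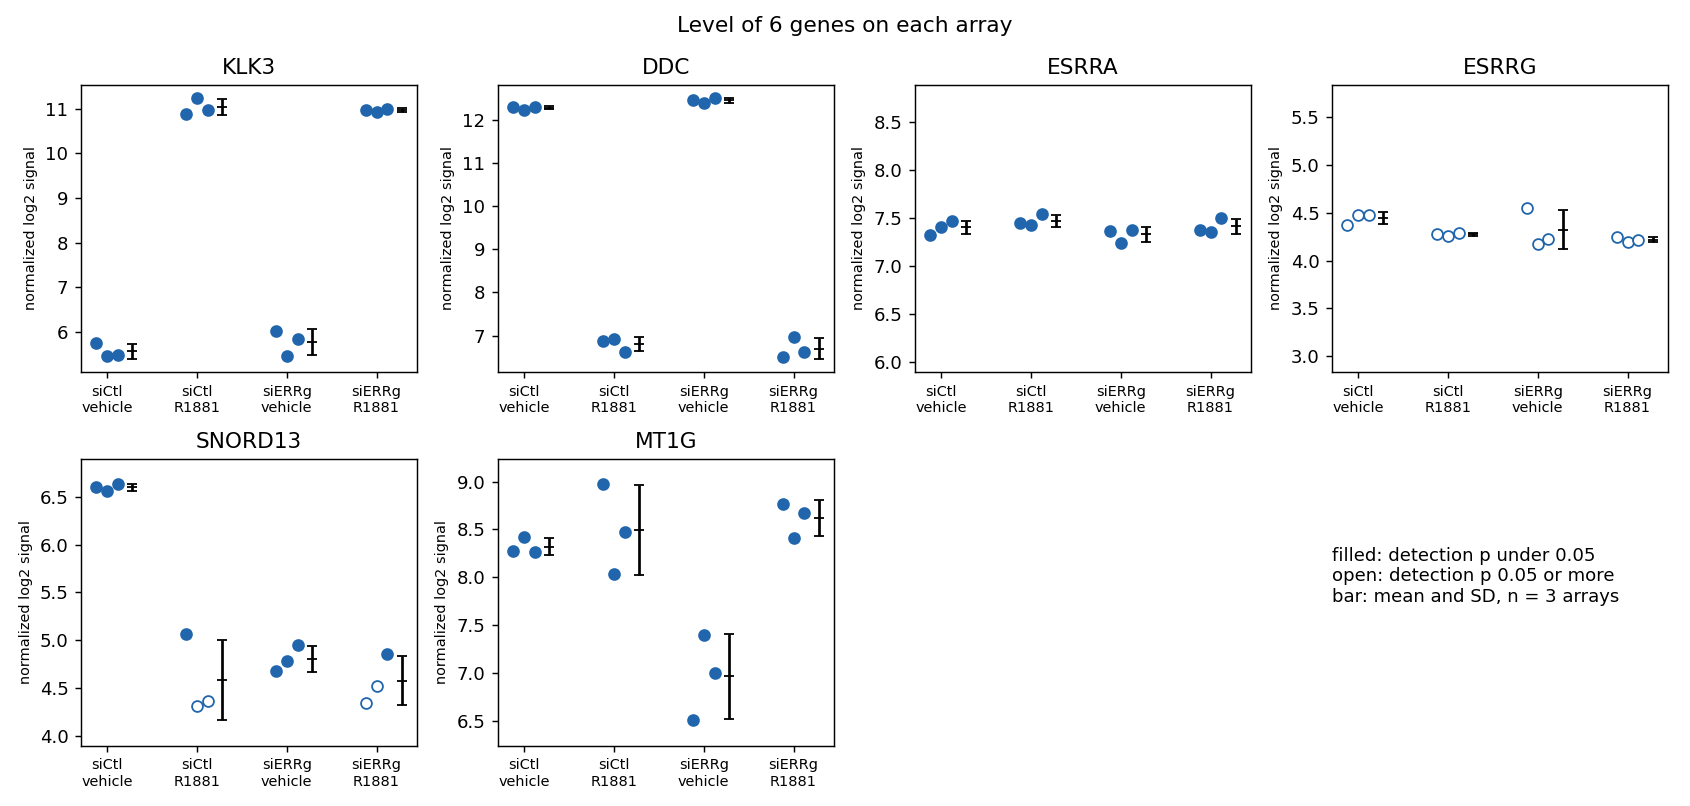
Normalized log2 level (vertical axis) of KLK3, DDC, ESRRG, ESRRA, SNORD13 and MT1G on each of the 12 arrays by group (horizontal axis), with filled points for a detection p under 0.05, open points otherwise, and the bar at the mean ± SD (n = 3). KLK3 lay at a mean of 5.561 under vehicle and 11.04 under R1881 with control siRNA, DDC at 12.27 and 6.802, and every ESRRG point is open.

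With control siRNA, R1881 raised KLK3, the gene of prostate-specific antigen, by 5.48 ± 0.14 (log2 change ± SE, n = 3 and 3; limma, adjusted p = 2.64e-12), or 44.5-fold, from 5.561 to 11.04. GNMT, which uses S-adenosylmethionine to methylate glycine, rose by 5.42 ± 0.14, or 42.7-fold. KLK2, a neighbouring kallikrein gene, rose at least 17-fold from below detection, and ORM1, an acute-phase plasma protein gene, at least 15.8-fold. The other large rises were in TUBA3E (at least 32-fold), TRIM51 (4.83), TUBA3D (4.55) and TRIM48 (4.23), whose near-identical copies the probes may not separate. DDC, which makes dopamine and serotonin from their precursors, fell by 5.47 ± 0.12 (adjusted p = 1.19e-12). CAMK2N1, an inhibitor of the kinase CaMKII, changed by -4.44 ± 0.15, the transglutaminase gene TGM3 by -4.24, and OPRK1, the kappa opioid receptor gene, by -4.04. CBLN2 changed by -4.07 and was detected on 2 of the 3 R1881 arrays, GASK1B changed by -3.79, COLCA1 fell at least 13.3-fold and the secreted phospholipase gene PLA2G2A at least 11.5-fold. Among 17011 genes tested, 6826 passed an adjusted p of 0.05 (40.1%), 3024 of them higher and 3802 lower under R1881. At least 2-fold changes numbered 1044, with 511 higher and 533 lower. The 3 R1881 arrays did not overlap the 3 vehicle arrays for 47.1% of genes, against 10% by chance.

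Of 108 measured genes on a list of androgen-induced genes, 95 rose, 2 fell and 11 did not pass, or 97 and 2 adjusted over the list alone, with a median of 1.56 (camera, adjusted p = 2.61e-48). FKBP5, a cochaperone of steroid receptors, rose by 4.08 ± 0.09 (adjusted p = 1.44e-12) and the membrane protease gene TMPRSS2 by 3.68 (1.54e-12). Of 37 androgen-repressed genes 23 fell and 13 rose, the same numbers adjusted over the list alone, with a median of -0.55 (adjusted p = 0.00226, and adjusted p = 0.0717 with an estimated correlation). BCHE, the butyrylcholinesterase gene, changed by -3.51, while HES6, a transcription factor gene on that list, rose by 2.80. MYC stood at 0.13 (adjusted p = 0.272). On the list of ERR family and coregulator genes, 1 of 11 rose and 4 fell, also adjusted over the list alone (median -0.034, adjusted p = 0.37). The coregulator genes NCOA1 (-0.96) and NRIP1 (-0.58) were among the 4, and ESRRA stood at 0.071 (adjusted p = 0.562).

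Among metabolic genes, cholesterol synthesis had the largest median with control siRNA: 20 of 25 rose and 2 fell, also adjusted over the list alone, with a median of 1.22 (camera, adjusted p = 3.08e-13). EBP, an enzyme of a late step of the pathway, rose by 2.06 and FDFT1, which makes squalene, by 1.62. Of 26 glycolysis genes 17 rose and 3 fell (18 and 3 adjusted over the list alone; adjusted p = 1.58e-05, and adjusted p = 0.0679 with an estimated correlation). SLC2A3, a glucose transporter gene, rose at least 14.5-fold, PFKFB2 at least 2.5-fold and LDHA, which turns pyruvate into lactate, by 1.36, while ENO2 changed by -1.74. Fatty acid and lipid synthesis had 14 of 29 higher and 5 lower (15 and 7 adjusted over the list alone; adjusted p = 7.22e-04, and adjusted p = 0.104 with an estimated correlation). There ACSL3, which activates fatty acids, rose by 2.91, FADS2 by 1.77 and LPIN1 by 1.73, and the desaturase gene SCD5 changed by -1.73. Of 9 pentose phosphate genes 6 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.00731, and adjusted p = 0.101 with an estimated correlation), with PRPS1 at 0.88, RPE at 0.82 and PGD at 0.37. The polyamine list had 7 of 13 higher and 2 lower, also adjusted over the list alone (adjusted p = 0.00141, and adjusted p = 0.0998 with an estimated correlation). SMS, which makes spermine, rose by 2.60, SAT1 by 2.48, and ODC1, which makes putrescine, by 1.72.

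For the TCA cycle and pyruvate entry, 12 of 36 genes rose and 6 fell with control siRNA, also adjusted over the list alone (camera, adjusted p = 0.0265, and adjusted p = 0.155 with an estimated correlation). IDH1 rose by 1.53, MPC2, part of the mitochondrial pyruvate carrier, by 1.5, PDK3, which inhibits pyruvate dehydrogenase, by 1.03 and ACLY, which makes acetyl-CoA from citrate, by 0.85. The call ended without replicate 2 of control siRNA under vehicle (adjusted p = 0.0585, within 0.00478 to 0.155 over 23 camera alternatives). Oxidative phosphorylation had 7 of 76 genes higher and 7 lower (6 and 3 adjusted over the list alone), a median of -0.050, a mean of -0.036 and a test direction upward (adjusted p = 0.821). NDUFB4 changed by -1.70, UQCR11 by 1.0 and NDUFV2 by 0.58. Fatty acid oxidation had 14 of 39 higher and 9 lower, also adjusted over the list alone (adjusted p = 0.132), with CROT at 1.25, ECI2 at 1.28, SLC25A20, the acylcarnitine carrier of mitochondria, at 1.15 and ACAD8 at 1.03. Serine and one-carbon metabolism had 7 of 22 higher and 5 lower, also adjusted over the list alone (adjusted p = 0.267), with SHMT1 at 1.09, TYMS at 0.94 and CTH at 0.83 beside GNMT. Solute carriers of ions, zinc and citrate, a list that holds 7 metallothionein genes, had 8 of 23 higher and 4 lower, 9 and 4 adjusted over the list alone (adjusted p = 0.0479, and adjusted p = 0.0993 with an estimated correlation). Of the lower genes 1 was a metallothionein, and without the 7 the list had a median of 0.33 (adjusted p = 0.0105, and adjusted p = 0.0611 with an estimated correlation), with the zinc transporter genes SLC39A10 at 1.44, SLC30A1 at 1.32 and SLC39A8 at -0.79. The call of the whole list ended without replicate 1 (0.0755) or 2 (0.0585) of control siRNA under vehicle, 1 (0.134) or 3 (0.0559) of control siRNA under R1881, 2 of ERRγ siRNA under vehicle (0.0506) or 1 of ERRγ siRNA under R1881 (0.0505). It lay between 0.0105 and 0.134 over its 24 camera alternatives.

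Most G1/S and G2/M genes rose with control siRNA. At G1/S and in DNA replication 31 of 47 rose and 0 fell at an adjusted p under 0.05 in limma, 34 and 0 adjusted over the list alone, with a median of 0.54 (camera, adjusted p = 4.04e-12). RRM2, a subunit of ribonucleotide reductase, rose by 1.54, CDC45 by 1.35, POLE2 by 1.17 and GINS3 by 1.16. At G2/M 50 of 54 rose and 0 fell, 52 and 0 adjusted over the list alone, with a median of 0.72 (adjusted p = 1.64e-18, and adjusted p = 0.0717 with an estimated correlation). Examples were the mitotic kinase gene MELK (1.36), the kinesin gene KIF20A (1.22), HMMR (1.12) and CDCA5 (1.01). Of 18 cell cycle inhibitors 6 rose and 7 fell, also adjusted over the list alone (adjusted p = 1), with CDKN2B at 2.19, CCNG2 at -1.56 and CDKN2C at -1.38. Protein glycosylation and secretion had 31 of 50 higher and 2 lower, 32 and 2 adjusted over the list alone, with a median of 0.40 (adjusted p = 1.99e-08). ST6GALNAC1, a sialyltransferase gene, rose by 3.18, and UAP1 and PGM3, enzymes that make UDP-N-acetylglucosamine, rose by 1.94 and 1.73. The unfolded protein response had 21 of 39 higher and 6 lower, 22 and 6 adjusted over the list alone (adjusted p = 5.96e-05), with the stress sensor gene ERN1 at 2.17, PDIA5 at 1.79 and ERO1A at 1.48. Hypoxia targets had 17 of 26 higher and 4 lower, also adjusted over the list alone (adjusted p = 7.67e-07), with NDRG1 at 3.92, BHLHE40 at 2.80 and ANKRD37 at 2.70. Ribosome biogenesis had 17 of 34 higher and 1 lower, 18 and 1 adjusted over the list alone (adjusted p = 6.48e-05), with NOP16 at 0.95 and IMP4 at 0.75.

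Mitochondrial ribosome and import genes had 34 of 93 higher and 4 lower with control siRNA, also adjusted over the list alone (camera, adjusted p = 6.53e-05, and adjusted p = 0.0801 with an estimated correlation). MRPS18A rose by 1.62 and MRPS23 and MRPL42 by 0.89 each. Antioxidant enzymes had 11 of 28 higher and 4 lower, also adjusted over the list alone (adjusted p = 0.0248, and adjusted p = 0.0998 with an estimated correlation), with GLRX2 at 1.82 and GSR, which reduces glutathione, at 1.27. Basal and mesenchymal markers had 4 of 10 higher and 0 lower in limma, also adjusted over the list alone (adjusted p = 0.00141, and adjusted p = 0.0679 with an estimated correlation). These were SNAI2 (at least 9.39-fold), ANXA1 (at least 3.61-fold), LAMA3 (1.22) and TWIST1 (1.08). That call ended when detection on all 12 arrays was required (0.0757, the highest of 6.94e-04 to 0.0757 over 23 camera alternatives). The lists of ATF4 targets, p53 targets, interferon response, neuroendocrine, luminal, fibroblast and leukocyte, apoptosis, steroid and housekeeping genes did not pass, with camera adjusted p from 0.0767 to 1. ATF4 targets had 6 of 30 higher and 11 lower, with ATF3 at 1.8 and the amino acid transporter gene SLC7A5 at -1.56, and p53 targets 5 of 26 higher and 11 lower, with SESN1 at -1.87. Interferon response genes had 4 of 34 higher and 9 lower, with HERC5 at 2.22 and MX1 at -1.27, and apoptosis genes 5 of 28 higher and 8 lower (5 and 9 adjusted over the list alone), with the survival gene MCL1 at -1.10. Luminal markers had 8 of 23 higher and 6 lower, also adjusted over the list alone, with a median of -0.011, a mean of 0.32 and a test direction upward (adjusted p = 0.176). KRT8, a keratin of luminal cells, rose by 1.74. Fibroblast and leukocyte markers had 1 of 10 higher and 3 lower, also adjusted over the list alone (median 0.030, mean -0.048, test direction upward, adjusted p = 1), with ACTA2 at 1.07 and VWF at -1.21. The 7 lists that kept their call with an estimated correlation, of 18 with the preset 0.01, were androgen-induced genes, cholesterol synthesis, G1/S, the unfolded protein response, glycosylation, ribosome biogenesis and hypoxia targets.

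**Figure D2:**
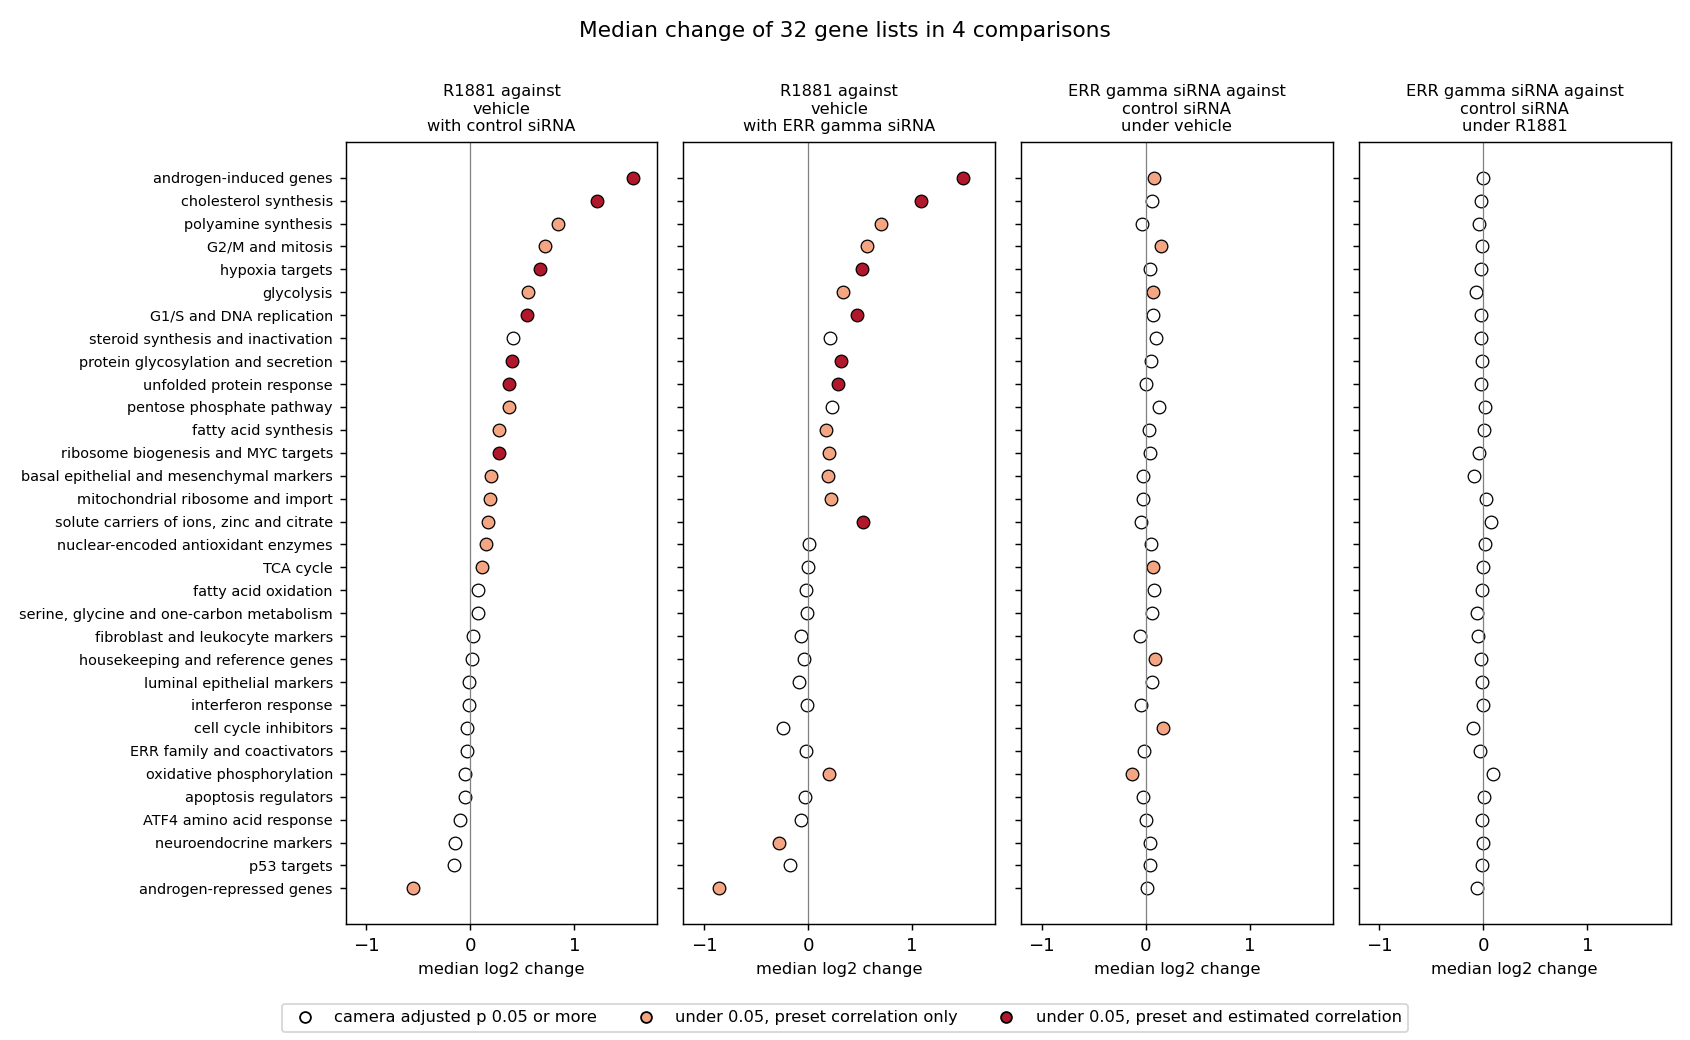
Median log2 change of each of the 32 gene lists (horizontal axis) in the 4 comparisons of 2 groups, one panel each, with white marks for a camera adjusted p of 0.05 or more, light marks for lists called with the preset correlation alone and dark marks for lists called also with an estimated one. Androgen-induced genes lay at 1.56 with control siRNA and 1.49 with ERRγ siRNA, and no mark is dark between the siRNAs.

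With ERRγ siRNA, R1881 raised KLK3 by 5.20 (log2 change; limma, adjusted p = 3.76e-12), or 36.9-fold, GNMT by 5.27, TUBA3E at least 32-fold, TRIM51 by 4.86, TUBA3D by 4.65, TRIM48 at least 20.3-fold, KLK2 at least 16.7-fold and the transcription factor gene MAF by 4.24. DDC fell by 5.75 ± 0.12 (SE, n = 3 and 3; adjusted p = 1.02e-12). CAMK2N1 (-4.55), TGM3 (-4.39), the membrane protein gene LRRN1 (-4.17) and OPRK1 (-3.96) also fell, PLA2G2A fell at least 13.3-fold, CBLN2 changed by -4.85 with detection on 1 of 3 R1881 arrays, and COLCA1 by -3.97 with detection on 2 of 3. FKBP5 rose by 3.82 and TMPRSS2 by 3.53. MYC changed by -0.34 ± 0.09 (adjusted p = 0.00595), a call that ended with median scaling (-0.092, adjusted p = 0.628, the highest of 3.04e-04 to 0.628 over 27 alternatives). A dimmer MYC probe, detected on all 12 arrays, stood at -0.274 and did not pass (limma over all probes without the detection filter, adjusted p = 0.0584). In all 6319 of 17011 genes passed (37.1%), 2835 higher and 3484 lower (44.9% higher), while with median scaling 3050 were higher and 2582 lower (54.2% higher). Among the 6319 were 469 higher and 489 lower by at least 2-fold. The arrays did not overlap for 49.4% of genes, against 10% by chance.

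With ERRγ siRNA, androgen-induced genes had 93 of 108 higher and 2 lower, 96 and 3 adjusted over the list alone (median 1.49; camera, adjusted p = 2.65e-48). Androgen-repressed genes had 21 of 37 lower and 12 higher, also adjusted over the list alone (median -0.86; adjusted p = 6.43e-04, and adjusted p = 0.0572 with an estimated correlation), with BCHE at -3.88, ST7 at -2.76 and HES6 at 2.83. Cholesterol synthesis had 20 of 25 higher and 1 lower, 21 and 2 adjusted over the list alone (adjusted p = 3.74e-13), with EBP at 1.81 and IDI1 at 1.67. Glycolysis had 14 of 26 higher and 3 lower, 14 and 4 adjusted over the list alone (adjusted p = 9.47e-04, and adjusted p = 0.108 with an estimated correlation), with SLC2A3 at least 13.5-fold higher and PFKFB2 at 1.73. Fatty acid and lipid synthesis had 14 of 29 higher and 3 lower, also adjusted over the list alone (adjusted p = 9.13e-04, and adjusted p = 0.117 with an estimated correlation), with ACSL3 at 2.73 and SCD at 1.35. Polyamine metabolism had 7 of 13 higher and 2 lower, also adjusted over the list alone (adjusted p = 0.001, and adjusted p = 0.0945 with an estimated correlation), with SAT1 at 2.38 and SMS at 2.24. Oxidative phosphorylation had 24 of 76 higher and 5 lower, also adjusted over the list alone, with a median of 0.20 (adjusted p = 0.00217, and adjusted p = 0.389 with an estimated correlation). UQCR10 rose by 1.03, UQCR11 by 0.77, NDUFB1 by 0.73 and NDUFB10 by 0.58. The list of solute carriers and metallothioneins had 15 of 23 higher and 3 lower, 16 and 3 adjusted over the list alone (median 0.53; adjusted p = 5.39e-04), and 6 of the 15 were metallothioneins. Without these the other 16 had 9 higher and 3 lower (median 0.41; adjusted p = 0.0191, and adjusted p = 0.0766 with an estimated correlation), with SLC39A10 at 1.59, SLC30A1 at 1.09 and SLC39A8 at -1.22.

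The TCA cycle list had 9 of 36 higher and 8 lower with ERRγ siRNA, also adjusted over the list alone (camera, adjusted p = 0.421), with MPC2 at 1.45 and IDH1 at 1.30. Pentose phosphate genes had 4 of 9 higher and 0 lower in limma, 4 and 1 adjusted over the list alone (adjusted p = 0.0501). For fatty acid oxidation the numbers were 12 and 8 of 39, 12 and 9 adjusted over the list alone, with a median of -0.021 against a mean of 0.073 and a test direction upward (adjusted p = 0.421). G1/S genes had 31 of 47 higher and 0 lower, 32 and 0 adjusted over the list alone (adjusted p = 3e-10), with RRM2 at 1.51 and CDC45 at 1.18. G2/M genes had 43 of 54 higher and 0 lower, 47 and 0 adjusted over the list alone (adjusted p = 1.21e-14, and adjusted p = 0.0945 with an estimated correlation), with KIF20A at 1.05 and MELK at 1.02. The unfolded protein response had 20 of 39 higher and 5 lower (adjusted p = 6.97e-05), glycosylation 26 of 50 and 3 (8.03e-07) and hypoxia targets 18 of 26 and 4 (6.7e-06). Adjusted over the list alone these were 21 and 5, 27 and 6, and 19 and 5, with ERN1 at 2.30, SPCS3 at 1.53 and NDRG1 at 3.89. Mitochondrial ribosome genes had 41 of 93 higher and 5 lower, 44 and 5 adjusted over the list alone (adjusted p = 2.35e-05), and ribosome biogenesis 14 of 34 higher and 3 lower, also adjusted over the list alone (adjusted p = 0.00927), each with an adjusted p = 0.0723 with an estimated correlation. Basal and mesenchymal markers had SNAI2, ANXA1, LAMA3 and TWIST1 higher again, 4 of 10 also adjusted over the list alone (adjusted p = 0.00337, and adjusted p = 0.0822 with an estimated correlation). Neuroendocrine markers had 5 of 10 lower and 1 higher, also adjusted over the list alone (median -0.28; adjusted p = 0.0239, and adjusted p = 0.084 with an estimated correlation). DDC, ENO2 (-1.47) and SYT4 (-0.72), a synaptotagmin gene, were among those that fell. That call ended with no detection filter (median -0.013, adjusted p = 0.174, the highest of 0.0108 to 0.174 over 23 camera alternatives). The other lists did not pass, with camera adjusted p from 0.104 to 0.916. Medians were below 0 and means above 0 for the serine (-0.011 and 0.20), luminal (-0.085 and 0.26), fibroblast and leukocyte (-0.068 and 0.012), apoptosis (-0.034 and 0.037) and housekeeping lists (-0.043 and 0.016), with a test direction downward for the last and upward for the others. ESRRA stood at 0.084 (adjusted p = 0.488).

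**Figure D3:**
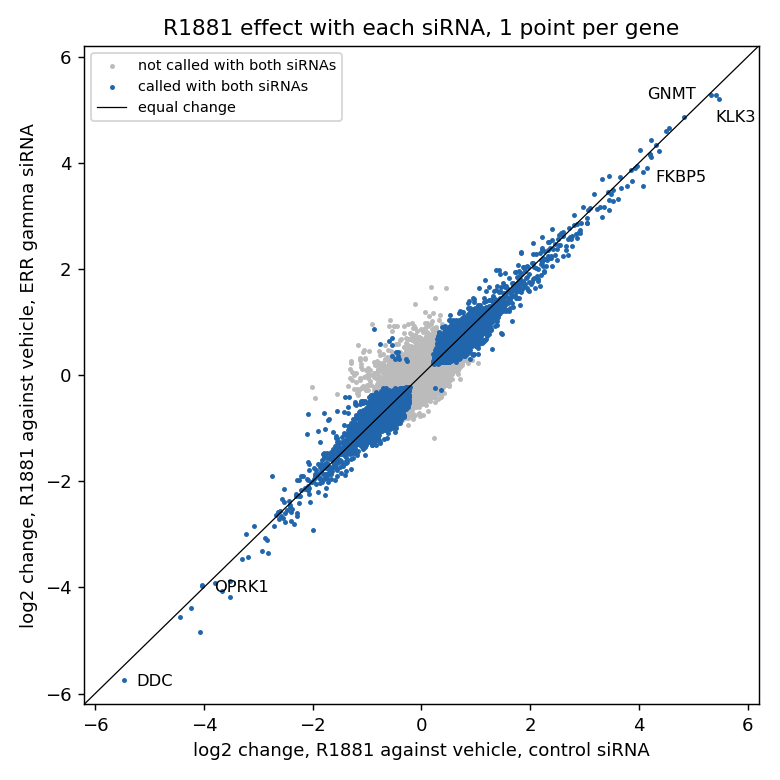
R1881 log2 change with control siRNA (horizontal axis) and with ERRγ siRNA (vertical axis), 1 point per gene, blue for the 4861 genes called with both, and a line where both changes are equal. Across the 17011 genes the correlation was 0.896, with KLK3 and GNMT at one end and DDC at the other.

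Under vehicle, ERRγ siRNA against control siRNA gave 46 genes that passed, 3 higher and 43 lower. With the replicate number as a block 6 passed, all lower, with normexp 515 (158 higher, 357 lower), without background correction 478 (174 higher, 304 lower), with the deposited normalized values 176 (64 higher, 112 lower) and with median scaling 133 (2 higher, 131 lower). SNORD13, a small nucleolar RNA needed for a modification of ribosomal RNA, changed by -1.79 ± 0.18 (SE, n = 3 and 3; limma, adjusted p = 0.00164), from 6.597 to 4.804. It passed in each of the 26 alternatives that gave it a value (adjusted p 1.06e-05 to 0.0239). RNA5S9, a 5S ribosomal RNA gene, changed by -1.06 ± 0.13 (adjusted p = 0.00595) and BCYRN1, a small brain cytoplasmic RNA, by -1.30 ± 0.20 (adjusted p = 0.0222). Whether the arrays measure such small RNAs evenly across samples was not tested. SNHG9, a snoRNA host gene, changed by -1.81 ± 0.35, MT1G, a metal-binding metallothionein gene, by -1.35 ± 0.23, TDP1, a DNA repair enzyme gene, by -1.18 ± 0.17 and the histone chaperone gene NPM3 by -1.06 ± 0.20. TMEM64 rose by 0.53 ± 0.09 and GOLGA7B at least 1.26-fold. By annotation 19 of the 46 are protein coding and 9 are long non-coding or small RNAs, 1 is a pseudogene, and 17 have no current class. The 3 arrays of each siRNA did not overlap for 22.3% of genes, against 10% expected by chance, and 2642 genes had an unadjusted p under 0.05. Genes that vary together can move such a share away from 10% by chance, and it was not computed for other splits of the arrays.

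The siRNA calls under vehicle varied with single arrays left out. Without replicate 1, 2 or 3 of control siRNA under vehicle 19, 4 or 1 genes passed, without replicate 1 or 3 of ERRγ siRNA under vehicle 5 or 3, without its replicate 2 82, and without replicate 1 or 2 of control siRNA under R1881 194 or 123; without replicate 3 of the latter 30 passed. In these leave-outs RNA5S9 was called in 11 of 12 (0.058 without replicate 3 of control siRNA under vehicle, within 1.22e-04 to 0.058 over 27 alternatives), TDP1 in 8, MT1G, BCYRN1 and TMEM64 in 7, and SNHG9, NPM3 and GOLGA7B in 3. With the mean of probes TDP1 stood at -0.29 (adjusted p = 0.22, the highest of 1.89e-04 to 0.22) and TMEM64 at 0.26 (0.281, the highest of 0.0127 to 0.281). The residuals of the 6 R1881 arrays shared an axis, with 37.9% of their variance, whose ends were replicates 1 (18.6) and 2 (-20.2) of control siRNA under R1881. On that axis the control siRNA arrays under vehicle lay at 3.21, 6.63 and 8.15 and the ERRγ siRNA arrays at -10.6, -1.18 and -6.19, and across genes, which are not independent replicates, its loadings correlated with the siRNA change under vehicle at -0.46. With the axis as a covariate 14 genes passed, 13 of them among the 46.

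With the preset correlation 7 lists were called between the siRNAs under vehicle in camera, and none with an estimated one (each adjusted p = 0.469). None of their members passed over all genes in limma. Oxidative phosphorylation had a median of -0.14 over 76 genes (adjusted p = 0.00182), with the complex I genes NDUFA3 at -1.16 (gene adjusted p = 0.103) and NDUFB1 at -0.49, the ATP synthase gene ATP5ME at -1.04 (0.0996) and COX7A2L at 0.36. G2/M genes had a median of 0.15 (adjusted p = 8.26e-04), with CDK1 at 0.50 (0.139) and ANLN at 0.42. The medians of the TCA cycle (0.072, adjusted p = 0.0111), cell cycle inhibitors (0.17, 0.027), androgen-induced genes (0.077, 0.0355), glycolysis (0.066, 0.0395) and housekeeping genes (0.090, 0.0395) were above 0. Among them LDHA stood at 0.41 (0.133), IDH3A at 0.36, CCNG2 at 0.41 (0.103) and CDKN2A at -0.54 (0.112). For these 7 lists 0 genes passed adjusted over the list alone, except 2 higher and 1 lower among cell cycle inhibitors. Without replicate 1 of ERRγ siRNA under vehicle the oxidative phosphorylation call ended (0.0658, within 1.41e-07 to 0.469 over 23 camera alternatives), without replicate 2 of control siRNA under vehicle those of G2/M (0.0873) and the TCA cycle (0.0605), and with the array axis as a covariate all 7. The remaining 4 calls each ended in 2 to 6 of the 12 leave-outs, at up to 0.154 for glycolysis without replicate 1 of control siRNA under vehicle.

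Adjusted over the list alone, the list of solute carriers and metallothioneins had 3 higher and 5 lower under vehicle (camera, adjusted p = 0.215). The 5 were metallothioneins, and the 7 metallothionein genes tested stood at -0.35 (MT1E) to -1.35 (MT1G). MT1A stood at -1.08 (limma, adjusted p = 0.0781), MT2A at -1.06 (0.0976), MT1X at -0.99 (0.0883) and MT1F at -0.78 (0.0883), and each of the 7 had an axis loading that matched the sign of its change. MT2A, MT1E and MT1H lie outside the rule for named genes and were chosen after their values were seen. Androgen-repressed genes had 4 higher adjusted over the list alone, hypoxia targets 2 higher, p53 targets 1 higher and 2 lower, apoptosis genes 2 lower, antioxidant enzymes 1 higher and 1 lower, neuroendocrine markers 1 higher and fibroblast and leukocyte markers 1 lower, with 0 over all genes. KLK3 stood at 0.21 (adjusted p = 0.514), FKBP5 at 0.074 (0.751), MYC at 0.23 (0.232), TMPRSS2 at 0.17 (0.389) and ESRRA at -0.073 (0.731).

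Under R1881, 0 of 17011 genes passed between the siRNAs in limma, and 1044 had an unadjusted p under 0.05. The smallest adjusted p was 0.191, and the arrays did not overlap for 10.9% of genes, against 10% by chance. FKBP5 stood at -0.19 (adjusted p = 0.844), KLK3 at -0.067 (0.966), MYC at -0.24 (0.731), TMPRSS2 at 0.023 (0.986) and ESRRA at -0.060 (0.947). The dimmer MYC probe stood at 0.0432. SNORD13 read 4.583 and 4.575 with control and ERRγ siRNA, near background, as it was detected on 1 of 3 arrays of each group. None of the 32 lists passed in camera: oxidative phosphorylation had the smallest adjusted p (0.103; median 0.093), and each estimated one was at least 0.946. In the mixed test, for changes in either direction, ATF4 targets had an adjusted p of 1.81e-07 in fry and 0.0138 by rotation (the next list 0.207 and 0.151), and for the siRNA main effect 8.73e-05 and 0.00864. In fry 7 lists passed the mixed test for the siRNA main effect (1 by rotation), 23 under vehicle and 8 for the interaction. Rotations were not run under vehicle or for the interaction, so those counts rest on the approximation of fry alone. Of the 30 ATF4 targets 1 was higher under R1881 and 4 lower at an unadjusted p under 0.05, with SLC7A11 at 0.38 (adjusted p = 0.685) and STC2 at -0.34 (0.666), named after their values were seen. Adjusted over the list alone 1 ribosome biogenesis gene was lower (POLR1A, -0.44; 0.604 over all genes) and 1 fibroblast and leukocyte marker higher (ACTA2, 0.41). Under this treatment the fit recovered 94% of 50 simulated genes changed by 1 on the log2 scale and 58% of those changed by 0.5. Genes with larger changes were simulated beside them and eased the threshold, so these shares may be too high where few genes change.

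The interaction asks whether the R1881 effect differed between the siRNAs. In limma 0 genes passed, 1884 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0956, for SNORD13 (1.78 ± 0.25), which was detected on 1 of 3 arrays in each R1881 group, so this value rests on readings near background. The next were PLA2G2D at 0.90 and C21orf58 at 1.05 (each 0.117), and NPW at 0.74 and SMCR5 at 0.78 (each 0.208), none of which passed. Simulated interactions of 1 on the log2 scale were recovered for 70% of 50 genes and of 0.5 for 10%. Here too larger changes were simulated beside them, so both shares may be too high where few genes differ. Without replicate 1 of control siRNA under R1881, 173 genes passed, and without replicate 2 of ERRγ siRNA under vehicle 1 passed. With normexp 79 passed (75 higher, 4 lower), with trended and robust variance 38 (37 higher, 1 lower) and without background correction 13, all higher. Over its 25 alternatives SNORD13 had an adjusted p of 0.00117 to 0.381 and passed in 9. Across genes, which are not independent replicates, the R1881 changes with both siRNAs correlated at 0.896 (rank correlation 0.766, slope 0.872), and 4861 genes were called with both, 2167 higher in both, 2679 lower in both and 15 opposite. Called with control siRNA alone were 1965 genes and with ERRγ siRNA alone 1458, none with a called interaction.

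For 9 lists the R1881 effect differed between the siRNAs with the preset correlation and for 0 with an estimated one (lowest adjusted p = 0.297). Oxidative phosphorylation genes had a median difference of 0.24 (camera, adjusted p = 8.21e-05, and adjusted p = 0.478 with an estimated correlation), and cell cycle inhibitors -0.22 (adjusted p = 0.00161, and adjusted p = 0.297 with an estimated correlation). Both were called in all 12 leave-outs and with the array axis as a covariate, under which the oxidative phosphorylation median was 0.14. The G2/M median was -0.14 (adjusted p = 0.00218, and adjusted p = 0.548 with an estimated correlation), a call that ended without replicate 2 of control siRNA under vehicle (0.0629, within 8.61e-07 to 0.548 over 23 camera alternatives). Medians were also below 0 for glycolysis (-0.16), the TCA cycle (-0.15), housekeeping (-0.14), androgen-repressed (-0.13), androgen-induced (-0.11) and ribosome biogenesis genes (-0.081), with adjusted p from 0.0226 to 0.0457 and from 0.297 to 0.542 with an estimated correlation. These 6 calls each ended in 4 to 8 of the 12 leave-outs, at up to 0.19 for androgen-induced genes without replicate 2 of control siRNA under R1881. With median scaling the medians of the TCA cycle (0.013), ribosome biogenesis (0.038) and housekeeping genes (0.038) were above 0. Over all genes 0 members of any list passed, while adjusted over the list alone the list of solute carriers had 5 higher, all metallothioneins, and 1 lower, androgen-repressed genes 2 lower, apoptosis genes 2 higher, cell cycle inhibitors 1 lower and fibroblast and leukocyte markers 1 higher.

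Averaged over both siRNAs, R1881 changed 8316 genes, 3714 higher and 4602 lower, and averaged over both treatments ERRγ siRNA changed 5, all lower. That count was 0 in limma in 7 of the 12 leave-outs and at most 9 in the others, with 1465 to 2692 genes at an unadjusted p under 0.05 over the 12. The count was 1 with the replicate number as a block and 0 with no detection filter (2809 genes at an unadjusted p under 0.05). Other settings raised it: 19 with normexp (4 higher, 15 lower), 14 without background correction (2 higher, 12 lower), 11 with the deposited normalized values (2 higher, 9 lower) and 10 with trended and robust variance (2 higher, 8 lower). Of those 5, SNORD13 was called in both (siRNA effect -0.90 ± 0.12, limma, adjusted p = 0.0424) along with 1 unnamed gene. That effect averages -1.79 under vehicle and -0.00856 under R1881, where SNORD13 read near background. Its siRNA call held in 2 of the 12 leave-outs, with a highest adjusted p of 0.151 without replicate 3 of control siRNA under vehicle. The effects of R1881 and of ERRγ siRNA, which are orthogonal contrasts of the same 12 arrays, correlated across genes at 0.0694 (rank correlation 0.0768; jackknife SE 0.0705), within that error of 0. The R1881 change with control siRNA and the siRNA change under vehicle, which share the same control arrays, correlated at 0.262. Simulated unchanged groups against the same controls gave 0.499, and the covariance was 0.0292 against a simulated 0.00936. Of the 46 genes called between the siRNAs under vehicle, 33 were also called for R1881, 31 lower in both against 9.61 for independent lists and 2 higher in both against 0.533. With ERRγ siRNA, whose vehicle arrays enter both changes with opposite sign, 23 of the 46 were called for R1881, 6 lower in both against 8.81 and 17 opposite, and the changes correlated at -0.112 (simulated -0.5). The 3 control arrays were not split, since 1 part would hold a single array, so part of this excess may come from the shared controls.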

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

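The tests that use the array axis, the tests of scaling for the 46 genes and the test of an siRNA effect that does not depend on R1881 were chosen after the results were seen; the test of scaling for oxidative phosphorylation and those of probes that read several genes and of other splits were not. Single arrays were weighed by leaving out each in turn and by array weights, and no other test of outlying arrays was made.

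In 9 gene lists the R1881 effect differed between the siRNAs by the interaction test in camera with the preset correlation, and in 0 with an estimated one, where every adjusted p was at least 0.297. The median difference (ERRγ minus control siRNA, log2) was 0.242 for oxidative phosphorylation (adjusted p = 8.21e-05), -0.223 for cell cycle inhibitors (0.00161), -0.145 for G2/M and mitosis (0.00218) and -0.146 for the TCA cycle (0.0226). It was -0.163 for glycolysis (0.0269), -0.133 for androgen-repressed genes (0.0329), -0.0807 for ribosome biogenesis (0.0329), -0.145 for housekeeping genes (0.0329) and -0.109 for androgen-induced genes (0.0457). No gene of these lists had a called interaction in limma over all genes, and 1884 of the 17011 genes had an unadjusted p under 0.05.

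The oxidative phosphorylation difference of 0.242 (SD over the 76 genes 0.415) combines a siRNA median of -0.136 under vehicle with one of 0.0933 under R1881. The tables argue against background correction and normalization as its whole cause, since the median lay between 0.193 and 0.392 in 4 other scalings. The array axis stays open, because with the axis as a covariate the median was 0.141 (SD 0.277) and the list was still called (adjusted p = 7.24e-04), between the sizes that would have argued for it or against it. With an estimated correlation the list was not called (adjusted p = 0.478). A response of these genes to the siRNA that depends on R1881 stays open and untested, because ESRRG itself was not detected.

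The 46 genes called between the siRNAs under vehicle had few counterparts under R1881, where 0 genes were called in limma and 1044 had an unadjusted p under 0.05. In 4 other scalings 46, 45, 44 and 37 of them were still called, with medians of -0.549 (SD 0.385), -0.49 (SD 0.35), -0.749 (SD 0.509) and -0.348 (SD 0.309). This argues against the choice among these scalings as the whole cause of their changes, although the 46 were picked with neqc on the same arrays. All kept their direction, but so did every gene that changed by over 0.25, so direction decides nothing. The number called and the share higher do depend on the scaling (133 to 515 called, up to 36.4% higher against 6.52%). The tables argue against an siRNA effect of that size that does not depend on R1881 for the 38 of the 46 detected on all 6 R1881 arrays. Of these 39.5% (15 of 38) changed in the same direction under R1881, with a median of 0.0288 (SD 0.164) against -0.676 under vehicle. Since the 46 were chosen by their vehicle change, the -0.676 may be too large, and 0 genes had a called interaction in limma. The direction of the 38 under R1881 is free of that choice. For the other 8, SNORD13 among them, levels under R1881 lie near background and an effect there stays open. On the array axis 82.6% of the 46 had a loading that matched their change. With the axis as a covariate their median change went from -0.714 (SD 0.517) to -0.681 (SD 0.41), or 95.4% of its size. But the 46 were called without the covariate, where a gene with a large loading has more residual spread and is less easily called. The 95.4% therefore cannot decide whether the axis was the cause. The calls fell from 46 to 14 and the genes with an unadjusted p under 0.05 from 2642 to 1705, while the median standard error stood at 0.122 and 0.123. The fit also has 1 fewer residual degree of freedom, and why the calls ended was not tested. An effect limited to vehicle, the axis, or another difference among the 6 vehicle arrays may account for the 46, and these cannot be separated with 3 arrays per group.

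All 7 metallothionein genes tested were lower with ERRγ siRNA under vehicle, with a median of -0.993 (SD 0.37), 1 of them called, and all 28 values in 4 other scalings were below 0 (-1.33 to -0.0654). The array axis stays open: 100% had a loading that matched their change, and with the axis as a covariate the median was -0.663 (SD 0.308), or 66.8% of its size. Near-identical transcripts read by several probes also stay open, since deviations from the group means correlated at 0.79 on average between these genes (0.395 to 0.976), so they may be fewer than 7 separate measurements. With R1881 and ERRγ siRNA, MT1G rose by 1.65 and MT1X by 1.64, and with control siRNA they stood at 0.172 and 0.451 (limma, adjusted p = 0.595 and 0.129). MT2A changed by -0.77 with control siRNA and stood at 0.376 with ERRγ siRNA (adjusted p = 0.275). None of the 7 had a called interaction (adjusted p 0.222 to 0.481). The R1881 changes with ERRγ siRNA use the same vehicle arrays as the siRNA changes above, so they are no separate observation. A response of metallothioneins to the siRNA stays untested beyond these arrays.

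For the comparisons of 3 against 3 arrays there are 10 splits, so a share under 0.05 is not possible. Only 1 of the 10, the real one, gave as many genes for R1881 with control siRNA (6826, highest other 0), for R1881 with ERRγ siRNA (6319, highest other 0) and between the siRNAs under vehicle (46, highest other 0). For lists likewise 1 of 10 gave as many (18 against 15, 17 against 11, and 7 against 2). Under R1881 all 10 splits gave 0 genes between the siRNAs in limma, as many as the real 0, which says nothing about chance. For the R1881 main effect 1 of 100 splits, the real one, gave 8316 genes, the highest other 11, so no other split came near the real count. The other splits mix R1881 with vehicle arrays, which raises their residual spread and keeps their counts low. The labels also do not show that the samples of a group are separate cultures, so this result holds for these samples only. For the siRNA main effect 3 of 100 gave as many as the real 5, the highest other 271. For the lists of the interaction 2 of 100 gave as many as the real 9, the highest other 9. Both shares lie under 0.05, but these splits exchanged siRNA labels within each treatment, so they cannot single out an interaction. Other splits gave 271 genes and 9 lists, and with an estimated correlation 0 lists of the interaction were called. Chance therefore stays open for both counts. The 5 were not stable, with 0 genes in limma in 7 of 12 leave-outs (1465 to 2692 at an unadjusted p under 0.05 over the 12). For the genes of the interaction the real count is 0 in limma, so 100 of 100 splits give at least as many by construction, which says nothing about chance; the highest other was 271. A split with 271 genes, several times the real counts, exchanged replicates 2 and 3 of control siRNA under R1881 with replicates 1 and 3 of ERRγ siRNA under R1881. It left the vehicle arrays in their real siRNA groups. On the array axis it set -20.2, -0.0275 and -3.98 against 18.6, 4.49 and 1.16, the same direction as ERRγ against control siRNA under vehicle. Why it gave so many calls was not tested.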

How the results depend on the processing

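The fit with the array axis as a covariate, the fit without both control siRNA arrays at its ends and the list of solute carriers without its metallothioneins were chosen after the data were seen; the other settings were planned. Among named genes, read on the same probe where all probes were kept, none that was called changed sign, and no called list changed its camera direction, but with median scaling the interaction medians of the TCA cycle (0.0129), ribosome biogenesis (0.0376) and housekeeping genes (0.0383) turned above 0, uncalled. Where a count moved, the cause was not tested, except that thresholds, filters and left-out arrays by construction change what is counted.

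R1881 counts stayed within 1.5 times of 6826 (control siRNA), 6319 (ERRγ siRNA) and 8316 (main effect), apart from the fold threshold of 1.5, which left 3056, 2841 and 2721. Leaving out single arrays gave 6014 to 6770, 5519 to 6585 and 7871 to 8226. With ERRγ siRNA 44.9% of the calls were higher, and 54.2% with median scaling.

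Between the siRNAs under vehicle, 46 genes became 515 with normexp (30.7% higher, against 6.52% of the 46), 478 without background correction (36.4% higher), 133 with median scaling (1.5% higher) and 176 with the deposited normalized table and the series matrix (36.4% higher). The 46 shared 46, 45, 44 and 37 genes with these. There were 26 with no detection filter, 104 with detection on all 12 arrays, 26 with the mean of probes, 295 with trend and robust variance, 240 with array weights, 124 with only the arrays of the 2 groups, 3 at an adjusted p under 0.01, 215 without both arrays at the axis ends and 14 with the axis as a covariate. Leaving out single arrays gave 1 to 194. Between the siRNAs under R1881 every setting and every left-out array gave 0 in limma.

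For the interaction, 0 genes became 79 with normexp, 13 without background correction, 2 with median scaling, 1 with the deposited table, 1 with the series matrix, 38 with trend and robust variance, 1 with array weights and 8 without both arrays at the axis ends, and 0 to 173 without single arrays. For the siRNA main effect, 5 became 19 with normexp, 14 without background correction, 11 with the deposited table, 11 with the series matrix, 0 with no detection filter, 3 with detection on all 12 arrays, 2 with all probes, 10 with trend and robust variance, 0 without both arrays at the axis ends, 3 with the axis as a covariate, 3 at 1.5-fold and 0 at an adjusted p under 0.01. Single arrays left out gave 0 to 9, with 9 without replicate 1 of control siRNA under R1881.

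With the replicate block, counts were 6661, 6123, 6, 0, 0, 8214 and 1 in the order of the 7 contrasts, so the siRNA counts went from 46 to 6 and from 5 to 1, and the block moved no other count of genes by over 1.5 times. Deviations of the 18 same-number pairs correlated at -0.258 to 0.128, 1 of them over 0.1, and 4 of 12 arrays correlated best with their own number. These values gave no sign that the numbers pair the samples, but with 3 arrays per group they cannot exclude it.

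Of the lists, 18 called for R1881 with control siRNA became 7 with an estimated correlation (16 to 18 without single arrays), and 17 with ERRγ siRNA became 7 with an estimated correlation and 27 with fry (17 to 18). For the R1881 main effect 17 became 8 with an estimated correlation and 28 with fry (16 to 17). Under vehicle, 7 between the siRNAs became 2 with median scaling, 0 with the axis as a covariate, 0 with an estimated correlation and 1 with fry. It was 2 to 7 without single arrays, with 3 and 2 without replicates 1 and 2 of control siRNA and 2 without replicate 1 of ERRγ siRNA. Under R1881, 0 became 1 with normexp, 2 without background correction, 1 with median scaling, 2 with the deposited table, 2 with the series matrix and 1 with the axis as a covariate (0 to 2 without single arrays). For the interaction, 9 became 4 with median scaling, 2 with the axis as a covariate, 0 with an estimated correlation and 5 with fry. It was 2 to 13 without single arrays, with 2 without replicate 2 of control siRNA under vehicle, 4 without replicate 2 of control siRNA under R1881, and 3 without replicate 3 of ERRγ siRNA under either treatment. For the siRNA main effect 0 became 1 with no detection filter and 1 with detection on all 12 arrays (0 to 1).

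The correlation of the main effects (0.0694) ran from 0.0074 to 0.11, left-out arrays included, and the ESRRG differences kept their sign and missed the threshold in every setting that gave them a value. Detection limits what these arrays show, since ESRRG lay at background throughout. Among named genes 14280 results were the same, 135 weaker, 178 stronger and 14 moved, and among lists 4914, 169, 94 and 206. The chip block was not run.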

Other observations

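No test in this part was chosen after its result was seen, but the small RNA genes RNU4ATAC and RNU4-2 were named after their values were. R1881 changed genes of steroid metabolism in both directions with either siRNA. UGT2B17 and UGT2B15, whose enzymes glucuronidate androgens, changed by -2.93 and -2.72 (log2) with control siRNA and by -3.31 and -2.83 with ERRγ siRNA, while UGT2B28 rose by 4.06 and 3.57. CYP3A5, a cytochrome P450 gene, rose by 1.89 and 2.02. Of 21 steroid metabolism genes 12 rose and 6 fell with control siRNA, also adjusted over the list alone (camera, adjusted p = 0.0767), and 9 rose and 4 fell with ERRγ siRNA, also adjusted over the list alone (adjusted p = 0.15). The UGT2B genes are near-identical in parts, so their probes may not read single genes; across the alternatives UGT2B17 with control siRNA ran from -3.08 to -2.76.

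Among the 46 genes lower or higher with ERRγ siRNA under vehicle, 3 of the 14 tested small nuclear and ribosomal RNA genes were called (RNA5S9, RNU4ATAC and RNU4-2), and 1 of the 115 small nucleolar RNA genes (SNORD13). Whether these arrays measure such small RNAs evenly across samples, or read other copies of them, was not tested. SNORD13 stood at 6.597 with control siRNA under vehicle and between 4.575 and 4.804 in the other 3 groups. It was detected on 1 of 3 arrays in each R1881 group, so those readings lie near background.

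Genes that neighbour each other in the genome had weakly correlated responses to R1881. Across 11951 adjacent pairs of different families, the R1881 main effects correlated at 0.147, and at 0.172 over all 12715 pairs. In 1000 random gene orders the correlation lay between -0.0324 and 0.0317 (permutation p = 0.001, the smallest they can give). Neighbouring pairs overlap, and genes are not independent replicates. Shared regulatory regions, overlapping transcripts or probes that read a neighbour may account for the correlation of 0.147, and none of these was tested.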
